A study of Mus musculus with 2 samples.

How the data were processed

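Gene expression in FACS-sorted mouse AgRP neurons was measured on 2 exon-level microarrays, 1 for FoxO1 knockout (KO) cells and 1 for cells with a heterozygous FoxO1 knockout. Each array was assigned to its genotype from the sample labels. Per the labels' protocols, total RNA was extracted with Trizol, and biotin-labelled cRNA was prepared by a Nugen protocol from age- and sex-matched littermates of mixed background. The number of mice behind each array, and whether animals were pooled, is not given in the sources used here.

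The deposited table holds 1 value per probe set and array, and its scale was taken from the values to be log2. Per the submitters' processing notes, the values were made with RMA (robust multi-array average: background correction, quantile normalisation and summary of the probes of a set) and Partek, with no versions. The values ran from 2.55 to 14.1 on the KO array and from 2.53 to 14.1 on the heterozygous array, with a median of 5.85 on both. Genome build and annotation release are not given in the sources used here, so no coordinates are printed, and the exon that a probe set lies in is not named. RMA as usually run forces all probe sets of both arrays to 1 distribution, so a change in total RNA does not show in such values, while a shift of the probe sets that name genes against the rest can remain.

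Of 1235936 probe sets, 318760 had 1 gene symbol in the platform annotation, 6684 had several, and 910492 had none there. Only probe sets with 1 symbol named a gene, which gave 22296 symbols. Gene summaries followed a rule fixed before the data were examined. A probe set was used where its mean over both arrays was at or above the median of that mean over all probe sets, a floor of 5.86 on the log2 scale. A probe set can pass this floor through 1 bright array while dim on the other, which favours large differences in genes with few bright probe sets. A gene's difference was the median of its probe sets' KO minus heterozygous differences, and its level on an array was the median of those probe sets there. Because the medians were taken separately, the difference need not equal the gap between the 2 levels. Genes with at least 3 such probe sets were evaluated, which gave 16639 genes with a median of 10 probe sets each. Of these symbols, 13959 were current in the RefSeq mouse gene table (assembly GRCm38.p6, used for names only), 2640 were an older symbol of 1 gene, and 40 matched no gene or several.

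A gene was called at least 2-fold higher or lower where its difference was at least 1 in size on the log2 scale and at least 75% of its probe sets went that way. With 1 array per genotype no test is possible, and no p-value or standard error is given. The SD printed beside a difference is over the gene's probe sets. It measures disagreement among probe sets of 1 pair of arrays, not the spread between mice, and the number of arrays limits the precision of every value.

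Before the data were examined, 26 gene lists with 423 different genes were fixed, of which 376 were evaluated, 4 under an older symbol. Each list's median difference was ranked among 10000 random lists of the same size, in which each member was replaced by 1 of the 200 evaluated genes nearest to it in level. The percentile describes these 2 arrays, since genes are not replicates, and the central range runs from 2.5 to 97.5. Named in the text are Foxo1, Gpr17, Agrp and Npy, the 12 genes with the largest difference in each direction past the 2-fold rule, and from each list up to 4 members past the rule or else its highest and lowest member. Unnamed gene models and olfactory, vomeronasal and taste receptor genes were left out of the 12. Other genes named were chosen after their values were seen, and the text says so.

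Alternatives fixed in advance were no floor, a floor at the 75th percentile, the mean over probe sets, at least 1 or at least 5 probe sets per gene, removal of the trend of the difference on level, a repeat of the quantile normalisation, centring of the arrays, and use of probe sets with several symbols. For the counts, a 1.5-fold rule and no rule on agreement were added, and for the lists the mean over members and random lists not matched on level. The gene summary was tested on simulated data for this comparison with 200 of 16639 genes changed. The rule took 92% of genes set to a log2 change of 1.5, 98% of those set to -1.5, 100% at 3 and 98% at -3, and 0.468% of the 16439 unchanged genes. Differences were shuffled there among probe sets of like level, so the simulation holds no variation of whole genes between samples. The 0.468% is thus not a rate of false calls for these arrays. Each probe set kept its mean over both arrays, so the effect of the floor was not simulated. Among 400 random lists of 12 genes, 5.25% fell outside the central range. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.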

Results

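AgRP neurons are hypothalamic cells that make agouti-related peptide and neuropeptide Y and drive feeding. FoxO1 is a transcription factor that insulin signalling keeps out of the nucleus. The series compared AgRP neurons collected by FACS from FoxO1 KO mice with cells from mice with a heterozygous FoxO1 knockout, which stand as the control. Its title names Gpr17, a G protein-coupled receptor, as a FoxO1 target in these cells, so the comparison asks which transcripts differ when FoxO1 is lost. There was 1 array per genotype and no replicate, so differences below are values of 2 arrays with no test. The arrays correlated at r = 0.920 over all probe sets and 0.868 over 16639 evaluated genes (across genes, which are not independent replicates). All differences are KO minus heterozygous KO on the log2 scale, with the SD over a gene's probe sets where one is given.

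Foxo1, the targeted gene, was lower on the KO array, with a level of 7.46 against 7.98 and a difference of -0.48 (SD 0.53 over 8 probe sets). All 8 of these probe sets were lower, by very different amounts. The largest differences were -1.56 (8.25 against 9.81) and -1.29 (9.79 against 11.1), and the smallest was -0.11 (8.67 against 8.77). The ninth Foxo1 probe set, under the floor, stood at 5.75 on the KO array and 4.79 on the heterozygous one. Foxo1 did not pass the 2-fold rule and stood at percentile 8 among the 1000 genes nearest to it in level. Its paralogs Foxo3, Foxo4 and Foxo6 had differences of -0.68, -0.58 and -0.39, so the Foxo1 difference was not set apart from theirs; these paralogs were named after their values were seen. Which Foxo1 probe sets lie in the deleted part is not known here, and a probe set outside it does not check the genotype. The difference was -0.71 with the floor at the 75th percentile and -0.33 with no floor.

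Gpr17 was lower on the KO array by 4.28-fold, with a difference of -2.10 (SD 1.48 over 5 probe sets) and levels of 6.40 against 8.67. Of its probe sets 4 were lower, at -3.25, -2.97, -2.10 and -0.53, and 1 was at 0.11. Agrp and Npy, the peptides that define the sorted cells, were among the brightest genes and differed little. Agrp stood at 12.4 on the KO array and 12.0 on the heterozygous one, a difference of 0.27 (SD 0.29, 6 of 7 probe sets higher). Npy differed by 0.14 (SD 0.19, 4 of 6 probe sets higher). Oligodendrocyte precursor and mature oligodendrocyte genes were lower together with Gpr17, with list medians of -0.53 and -1.02.

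**Figure D1:**
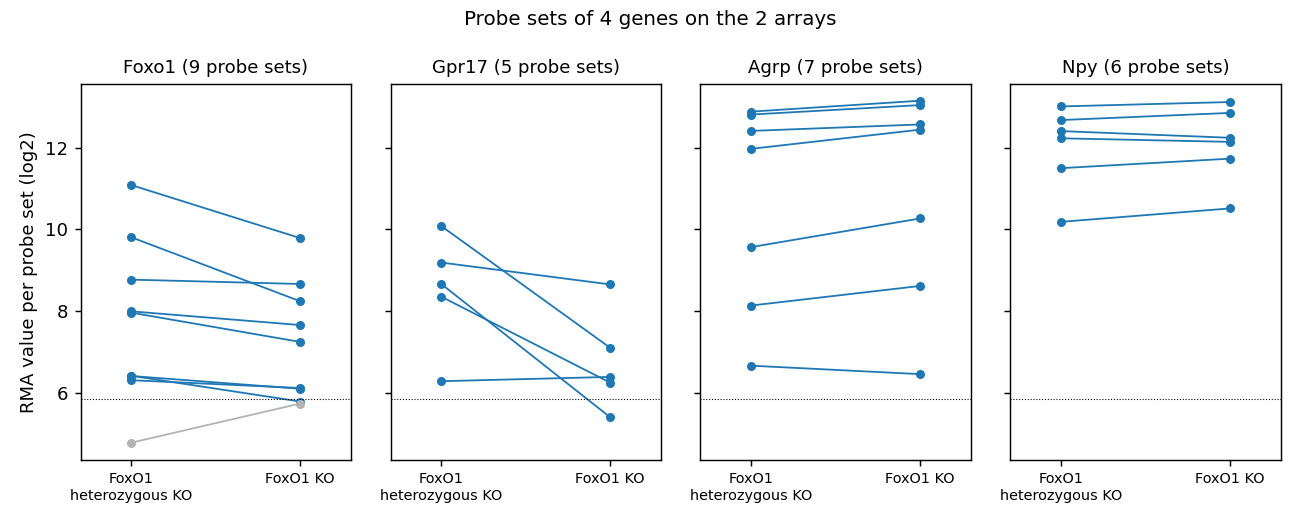
RMA values (log2, y axis) of each probe set of Foxo1, Gpr17, Agrp and Npy on the heterozygous KO array and the KO array, 1 line per probe set, with the floor of 5.86 dotted and the Foxo1 probe set under it in grey. All 8 Foxo1 probe sets above the floor and 4 of 5 Gpr17 probe sets were lower on the KO array, while 6 of 7 for Agrp and 4 of 6 for Npy were higher.

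Across all evaluated genes, 188 were at least 2-fold higher on the KO array and 186 at least 2-fold lower, or 1.13% and 1.12%. Of these, 18 were at least 4-fold higher and 24 at least 4-fold lower. The median difference over genes was -0.11 (quartiles -0.29 and 0.09), and 10841 genes lay below 0 against 5794 above. With differences centred on that median, an alternative chosen after seeing the data, 270 genes were higher and 127 lower. The median SD over the probe sets of a gene was 0.68.

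The 12 genes with the largest higher values under the rule included Cd36, a fatty acid translocase, at 3.77 (SD 2.55 over 4 probe sets, 8.59 against 4.82). Pole4, a DNA polymerase epsilon subunit, was at 3.16 and EG226654, an older symbol of Tstd1, at 3.04. Mitochondrial genes among the 12 were Mrpl22, a ribosomal protein of the organelle, at 2.33, Tfb1m, which methylates its ribosomal RNA, at 2.17, and Pdss1, an enzyme of coenzyme Q synthesis, at 2.20. Dbi, the acyl-CoA binding protein and diazepam binding inhibitor, stood at 2.19 with levels of 10.2 against 8.84. The others were the pseudogene Hsp25-ps1 at 2.44, Calml4 at 2.36, Nipsnap3a at 2.32, Zmat4 at 2.25 and the noncoding RNA Snhg6 at 2.07. Several of these rest on few probe sets, which passed the floor on the mean of both arrays through the KO array: the heterozygous levels of Cd36 (4.82), Pole4 (5.01), Calml4 (4.81) and EG226654 (5.85) were under the floor of 5.86, so the sizes and order of these genes are uncertain. With no floor, Cd36 stood at 0.04 over 23 probe sets, Pdss1 at 0.19, Zmat4 at 0.51, Pole4 at 0.55, Nipsnap3a at 0.99 and Dbi at 2.07, and none of these 6 passed the rule. Tfb1m stood at 1.44 and EG226654 at 1.92 there and passed, while Mrpl22 kept its 2.33 with the floor at the 75th percentile and lost the call because under 75% of its 7 probe sets there were higher.

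Slc17a6, the vesicular glutamate transporter of most hypothalamic excitatory neurons, was among the 12 genes with the largest lower values, at -4.29 (SD 2.32 over 11 probe sets, 5.40 against 9.11). Its KO level was under the floor, as were those of Gje1, BC030500, Zc3h8, Cacng3, Zfp58 and Npvf, so their sizes and order are uncertain too. Ugt8a, the enzyme of myelin galactolipid synthesis, was at -2.98 (SD 1.15, 7 of 7 probe sets lower). Pdgfra, the growth factor receptor of oligodendrocyte precursors, was at -2.41 (SD 1.56, 26 of 27 probe sets lower). Gje1, a connexin symbol that has also been used for the oligodendrocyte connexin gene Gjc3, was at -3.33 (SD 0.87 over 5 probe sets). Further neuronal genes were Npvf, a hypothalamic RFamide neuropeptide precursor, at -2.36, and Cacng3, an AMPA receptor auxiliary subunit, at -2.57. The remaining 6 were BC030500 at -3.18, Zc3h8 at -2.62, Zfp58 at -2.56, the retinoic acid binding protein Crabp2 at -2.43, Samd12 at -2.32 and the fatty acid elongase Elovl7 at -2.27. With no floor Slc17a6 stood at -1.15 over 20 probe sets and Crabp2 at -1.34, both past the rule, while BC030500 at -1.40, Elovl7 at -0.66 and Zc3h8 at -0.04 were not. Zfp58 ran from -2.62 to -1.29 over the alternatives that evaluated it and passed the rule in each.

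**Figure D2:**
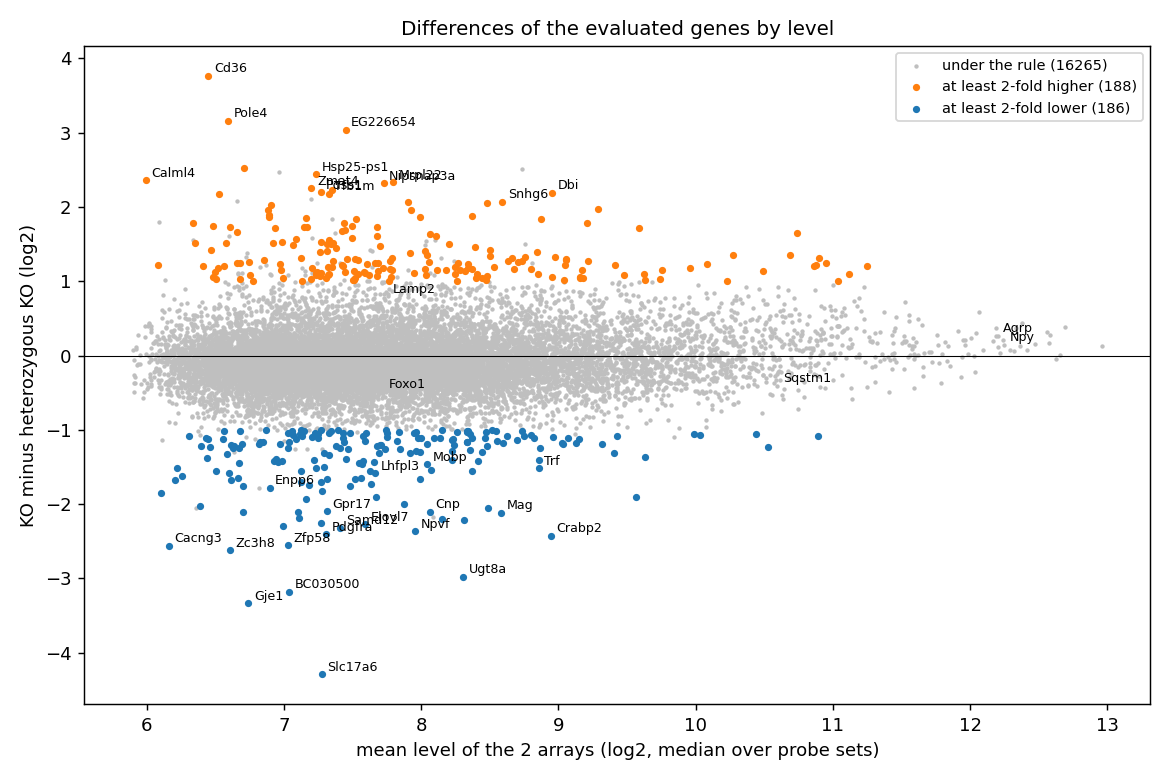
Difference of each evaluated gene (KO minus heterozygous KO, log2, y axis) against its mean level on the 2 arrays (log2, x axis), 1 point per gene, with genes at least 2-fold higher in orange and at least 2-fold lower in blue. The 188 higher and 186 lower genes lie at low and middle levels for the most part, and Agrp (0.27) and Npy (0.14) lie near 0 at the bright end.

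Markers of cell types were compared next, since sorted cells can carry RNA of their neighbours. The 12 genes of AgRP neuron identity had a median of 0.14 (percentile 93.1), with 8 above 0 and none past the rule; the melanocortin receptor Mc3r was highest at 0.52 and the ghrelin receptor Ghsr lowest at -0.60. All 11 evaluated mature oligodendrocyte genes were below 0, with a median of -1.02, against a central range of random lists from -0.32 to 0.14 (percentile 0). Of these, 6 were at least 2-fold lower, led by the myelin genes Mag at -2.12 (SD 1.31, 13 of 14 probe sets lower) and Cnp at -2.10 (SD 1.02, 6 of 6), with Trf, the iron carrier, at -1.52 and Mobp at -1.46. All 12 oligodendrocyte precursor genes were below 0 too, with a median of -0.53 (percentile 0), and 3 passed the rule, which were Pdgfra, Enpp6 at -1.78 and Lhfpl3 at -1.59. Both oligodendrocyte lists stayed below percentile 2.5 under each of the 11 alternatives.

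Medians of the other cell types lay closer to 0. The astrocyte list had a median of -0.20 (percentile 18.1, Gfap 0.66, Slc1a3 -0.73), tanycyte and ependymal genes -0.15 (percentile 35.5, Tmem212 0.53, Vim -0.46) and microglia and macrophage genes -0.07 (percentile 70.7, Aif1 0.50, Trem2 -0.30). All 10 evaluated endothelial and pericyte genes were below 0, with a median of -0.25 (percentile 6.84, Pecam1 -0.05, Cdh5 -0.77), and this percentile was under 2.5 in 4 of 11 alternatives. The 3 evaluated erythroid genes had a median of 0.32 (percentile 97.7, inside the central range in 4 of 9 alternatives, lowest 96.6), with the beta globin gene Hbb-b1 at 1.05; Hbb-b1 did not pass the rule at 0.87 with no floor or at 0.85 with probe sets of several symbols. Among 16 genes of other hypothalamic neurons the median was -0.12 (percentile 45.8), yet 2 were at least 2-fold lower, Slc17a6 and the oxytocin gene Oxt at -1.01 (SD 2.57 over 5 probe sets). Oxt did not pass at -0.74 with the floor at the 75th percentile or at -0.94 with the trend on level removed. With the mean over members in place of the median this list stood at percentile 0.12. Pan-neuronal genes had a median of -0.16 (percentile 15.5, Elavl4 0.13, Nefl -0.90), with percentile 1.08 by the mean over members.

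**Figure D3:**
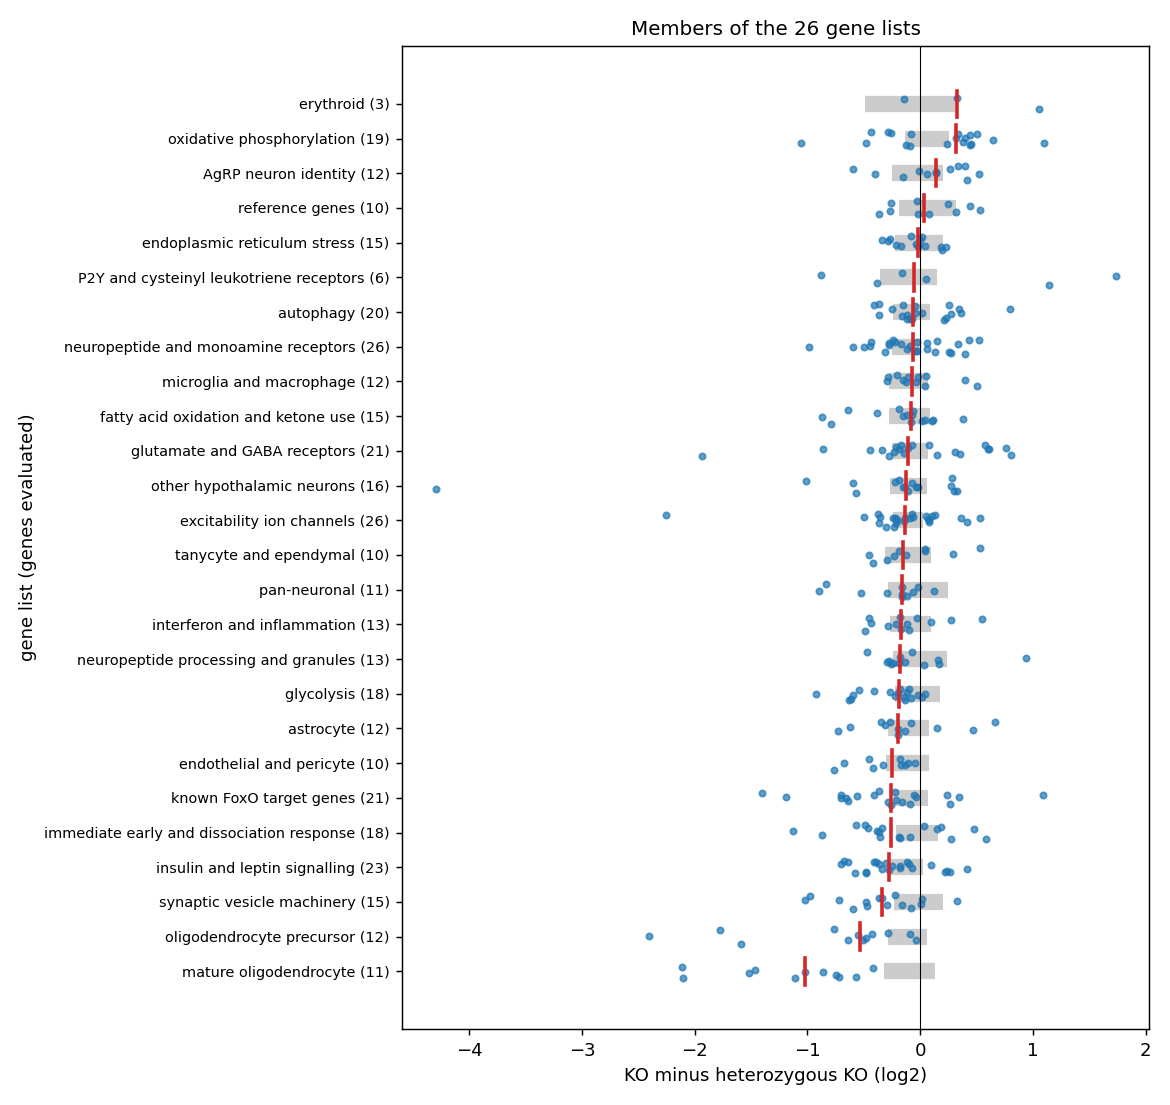
Differences of the evaluated members (dots, KO minus heterozygous KO, log2, x axis) of each of 26 gene lists (y axis, number of genes evaluated in brackets), with the list median as a red bar and the central 95% of medians of random lists of like level as a grey band. The median bars of the mature oligodendrocyte (-1.02) and oligodendrocyte precursor (-0.53) lists lie left of their bands, and those of the AgRP neuron identity (0.14) and reference gene (0.03) lists lie inside them.

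FoxO targets and insulin signalling genes were lower as lists by small amounts. The 2 lists share Insr and Irs2, so their percentiles are not separate results. Over all evaluated genes, 10841 of 16639 were below 0. Of 21 evaluated FoxO target genes, 17 were below 0, with a median of -0.26 (percentile 1.24). The cell cycle inhibitor Cdkn1a at -1.41 (SD 0.95, 5 of 5 probe sets lower) and the mitophagy receptor Bnip3 at -1.19 (SD 1.00, 8 of 10) passed the rule; Bnip3 was at -0.99 with no floor. The highest member, Pdk4, a kinase that inhibits pyruvate dehydrogenase, ran the other way at 1.09 (SD 1.89). Its 4 of 6 probe sets higher were too few for the rule, and it was named after its value was seen. Agrp, which this list also holds, was among the 4 members above 0, at 0.27 (6 of 7 probe sets higher). The insulin and leptin signalling list had a median of -0.27 (percentile 1.22), with 18 of 23 genes below 0 and none past the rule. The insulin receptor Insr was lowest at -0.70 and the leptin receptor Lepr highest at 0.41 (21 of 27 probe sets higher). Neither list was outside the central range under every alternative: the FoxO targets stood at percentile 7.78, and the insulin and leptin genes at 8.65, with the floor at the 75th percentile.

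Receptor and channel lists lay inside the central range of the random lists, the P2Y list not under every alternative. Neuropeptide and monoamine receptors had a median of -0.07 over 26 genes (percentile 82.5), with Mc3r at 0.52 and the cholecystokinin receptor Cckar at -0.98. Cckar passed the rule at -1.02 with no floor and at -1.16 with the mean over probe sets. The list of P2Y and cysteinyl leukotriene receptors, the closest relatives of Gpr17, had a median of -0.06 over 6 genes (percentile 69.1). All 6 were P2Y receptors, since P2ry4, Cysltr1 and Cysltr2 were not evaluated. By the mean over members the list stood at percentile 98.5, and with at least 5 probe sets per gene its median was 1.15 over 3 genes (percentile 99.97). Of the 6, P2ry13 at 1.73 (SD 1.57, 4 of 5 probe sets higher) and P2ry14 at 1.15 (SD 1.20, 6 of 8) were at least 2-fold higher, opposite in direction to Gpr17. P2ry12 was at 0.05. P2ry1 at -0.88, P2ry6 at -0.38 and P2ry2 at -0.16 went the same way as Gpr17, none past the rule. P2ry14 stood at 0.08 over 3 probe sets with the floor at the 75th percentile. Glutamate and GABA receptors had a median of -0.11 over 21 genes (percentile 48.8), with the metabotropic receptor Grm5 at -1.93 (SD 1.15, 12 of 13 probe sets lower) the 1 member past the rule. Ion channels of excitability had a median of -0.14 over 26 genes (percentile 35), with the cation channel Trpc5 at -2.25 (SD 1.92 over 4 probe sets). With no floor Grm5 stood at -0.78 and Trpc5 at -0.34, and neither passed.

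The 15 synaptic vesicle genes had a median of -0.34 (percentile 0.105), with 12 below 0 and the complexin gene Cplx2 at -1.02 (SD 0.71, 12 of 13 probe sets lower). The list stayed below percentile 2.5 in 11 of 11 alternatives, while Cplx2 did not pass the rule under 4 alternatives, at -0.77 to -0.95. Genes of neuropeptide processing and granules had a median of -0.18 over 13 genes (percentile 7.5, Prcp 0.94, Cadps -0.47). Immediate early and dissociation response genes had a median of -0.26 over 18 genes (percentile 0.59, or 5.36 with at least 5 probe sets per gene), with Egr3 at -1.13 (SD 0.29, 4 of 4 probe sets lower) the 1 member past the rule.

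Oxidative phosphorylation genes were higher as a list, with a median of 0.32 over 19 genes (percentile 99.4), 11 above 0 and 8 below. Of the complex I subunits, Ndufa1 was at 1.10 (SD 0.45, 3 of 3 probe sets higher) and Ndufv1 at -1.06 (SD 0.73, 10 of 12 lower), so 1 member passed in each direction; Ndufv1 was at -0.85 with the mean over probe sets. By the mean over members the list stood at percentile 72.7, and it lay inside the central range in 3 of 11 alternatives. Glycolysis genes had a median of -0.19 over 18 genes (percentile 5.26, Slc2a3 0.04, Pfkl -0.92), with 16 below 0 and a percentile of 0.26 by the mean over members. Fatty acid oxidation and ketone use genes had a median of -0.08 over 15 genes (percentile 61.2, Acadm 0.38, Acadl -0.87) and autophagy genes -0.06 over 20 (percentile 65.0, Lamp2 0.80, Sqstm1 -0.41). Lamp2 passed the rule at 1.13 with the mean over probe sets, as did Cdh5 at -1.16. Endoplasmic reticulum stress genes had a median of -0.02 over 15 (percentile 51.6, Xbp1 0.23, Herpud1 -0.34), interferon and inflammation genes -0.17 over 13 (percentile 24.2, B2m 0.55, H2-K1 -0.48) and reference genes 0.03 over 10 (percentile 45.0, Rpl13a 0.53, Tfrc -0.37).

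Of the 26 lists, 8 lay outside the central range, 6 below and 2 above, where 1.3 would fall outside by chance if the members of a list varied independently of each other. Members of a list can shift together for any difference between 2 samples, and some lists share members. Thus 8 against 1.3 does not measure an effect of genotype. Of these 8, 3 were outside under every alternative run (mature oligodendrocyte, oligodendrocyte precursor and synaptic vesicle genes) and 5 were inside in at least 1. Centring on the median over genes adds 0.11 to every gene, so list medians between -0.11 and 0 then lie above 0 by construction, while their percentiles are not affected.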

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

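All tests in this part were chosen after the result was seen. The first result lies in probe sets without a gene symbol, which are not summarised in any gene or list value above. They do enter the floor and the correlation over all probe sets. They also enter the alternatives of trend removal, repeated quantile normalisation and centring of the arrays. Of the probe sets without a symbol, 12111 of 398179 above the floor were at least 4-fold higher on the KO array, or 3.04%, against 5776 lower, or 1.45%. Among probe sets with 1 symbol the shares were 2.56% and 2.60%.

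Gpr17 was lower together with the oligodendrocyte lineage, where the 23 markers of both fixed lists had a median of -0.75 and ran from Pdgfra, Mag and Cnp, 3 markers as low as Gpr17, to Sox10 at -0.09 (4 of 9 probe sets higher) and Cspg5 at -0.04 (9 of 18). For a loss of every non-neuronal cell type by like amounts in the KO sort, the lineage median was set against 44 markers of astrocytes, tanycytes, microglia and vessels (median -0.16). The gap was -0.58, against a lower bound of -0.25 for random divisions of the markers, although all 10 vessel markers were below 0 too. The divisions did not match markers on level, and several other markers were dim on the heterozygous array (Gfap 7.09, Pecam1 6.79, against Cnp 9.46), with less room to fall. Of the brighter ones, Aldoc (10.6 there, also held by the glycolysis list) and Crym (8.12) differed little, at -0.19 and 0.05. Vim (9.83), Rgs5 (8.43), S100b (8.31), Ccdc153 (8.28) and Cdh5 (8.03) were lower, at -0.46, -0.46, -0.35, -0.30 and -0.77. Some dim lineage markers were lower too (Aspa at 6.32 there, difference -0.72). The markers thus did not fall equally, but such a loss is not excluded. Less oligodendrocyte lineage RNA on the KO array stays open but was not put to an independent test, since its markers are the pattern itself. Every one of these markers was below 0, but Sox10 and Cspg5 lay above the median over all evaluated genes, which was -0.11. A sort for AgRP neurons would be meant to remove such cells, yet markers such as Cnp (9.46) and Trf (9.36) were bright on the heterozygous array. Mbp, an abundant myelin transcript, was at 8.68 against 9.52, 0 of the 23 markers are held by another list, and how many of them AgRP neurons express was not examined. A lower Gpr17 within AgRP neurons after FoxO1 loss may add to this or may be the whole of the Gpr17 difference, and with 1 array per genotype these explanations cannot be told apart for Gpr17.

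The count of genes past the 2-fold rule was set against groupings of probe sets drawn at random from those of like level. Over 100 such groupings, the number of genes higher had a median of 44 and a highest value of 59, against 188 observed. The number lower had a median of 80.5 and a highest value of 98, against 186 observed. Independent noise of single probe sets is thus argued against as the whole cause, and it could still account for part of both counts. No biological explanation of the count was tested.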

How the results depend on the processing

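Centring on the median over genes was the 1 alternative chosen after seeing the data. Among genes named by the rules fixed in advance, no direction of a gene past the rule turned under any alternative that evaluated it. Gfap, Elavl4, Xbp1, Slc2a3 and Pecam1, which were under the rule, changed sign under an alternative, with Gfap running from -0.03 to 0.94. Of 43 genes past the rule that were named by the rules fixed in advance, 25 passed under every alternative that evaluates them, and of 32 under it 3 passed in some. Single genes named only after their values were seen, such as Tac1, Nova1 and Rps27, were not followed through the alternatives. Foxo1 ran from -0.71 to -0.33 and Gpr17 from -2.10 to -1.75; Gpr17 has too few probe sets with the floor at the 75th percentile and was not evaluated there. Genes at least 2-fold higher and lower numbered 338 and 329 with at least 1 probe set per gene, since more genes are evaluated (20521), and 545 and 815 with a 1.5-fold rule. The other counts ran from 142 to 270 higher and from 126 to 254 lower. Of list medians 255 values stayed within the SD over the list's members of the main value. Of list percentiles 258 stayed on the same side of the bounds of the central range and 25 did not. Some of the 258 still moved far, as for neuropeptide and monoamine receptors, at 82.5 and as low as 22.8 under an alternative. For the moves that follow the cause was not tested. By the mean over members, percentiles were 0.12 for other hypothalamic neurons, 1.08 pan-neuronal, 97.46 erythroid, 5.4 insulin and leptin, 98.5 P2Y, 72.7 oxidative phosphorylation and 0.26 glycolysis. With no matching on level, AgRP identity stood at 98.9 and erythroid at 96.6. With the floor at the 75th percentile, endothelial stood at 2.03, FoxO targets 7.78, insulin and leptin 8.65, oxidative phosphorylation 96.8 and interferon 0.61, its median -0.48 over 5 genes. With the mean over probe sets, endothelial stood at 0.91, insulin and leptin 3.87 and oxidative phosphorylation 97.0. With at least 5 probe sets, endothelial stood at 1.5, FoxO targets 4.09, immediate early 5.36 and P2Y 99.97, its median 1.15 over 3 genes. Without the floor, insulin and leptin stood at 5.33. With at least 1 probe set, erythroid stood at 96.7, and with probe sets of several symbols at 97.4, where endothelial stood at 0.905. Dim probe sets limit genes such as Cd36, whose value was 0.04 without the floor.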

Other observations

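The gene families below and the genes named in them were chosen after their values were seen, as were all tests in this part. Cytosolic and mitochondrial ribosomal protein genes and complex I subunits were higher on the KO array as families. Of 46 cytosolic ribosomal protein genes, 41 were above 0, with a median of 0.38 (percentile 100 among random lists of like level), and 4 were at least 2-fold higher, among them Rps27 at 1.71 (SD 0.26, 3 of 3 probe sets higher) and Rpl39 at 1.66 (SD 0.37, 9 of 9). Of 70 mitochondrial ribosomal protein genes, 52 were above 0, with a median of 0.20 (percentile 100), and 5 passed the rule, among them Mrps36 at 1.34 and Mrps28 at 1.32. Complex I subunits had a median of 0.37 over 33 genes, 28 of them above 0. Of these subunits, 3 were at least 2-fold higher, among them Ndufb2 at 1.39 (SD 0.48, 8 of 8 probe sets higher), and 1 was at least 2-fold lower, Ndufv1 at -1.06. Proteasome subunits had a median of 0.07 over 38 genes (percentile 87.5). The 239 zinc finger genes named Zfp, with a median of -0.06 and 99 above 0, stood at percentile 99.8 against a random median of -0.12, so in large families a percentile near 100 can go with a small shift. Many ribosomal protein genes have processed pseudogenes that probe sets can also bind, so their single values are uncertain.

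Single genes of known neuronal or myelin function past the rule, picked after their values were seen, form no tested group. Tac1, the substance P precursor, was at -2.20, the calcium-binding protein gene Calb1 at -1.74, the orphan receptor gene Gpr101 at -1.66 (7 of 7 probe sets lower), Ddc, the decarboxylase of dopamine and serotonin synthesis, at -1.55 (12 of 12 lower), and the neuronal splicing factor gene Nova1 at -2.21. Npffr2, a receptor for RFamide neuropeptides, was higher at 1.73 (SD 1.65, 3 of 4 probe sets higher), and the fixed list of other hypothalamic neurons lay at percentile 45.8. The GABA neuron genes Gad1, Gad2 and Slc32a1 were at -0.15, 0.14 and -0.40, none past the rule. Bcas1, a gene of myelinating oligodendrocytes, was at -1.91, Fa2h, an enzyme of myelin lipids, at -1.43, and the myelin protein gene Pllp at -1.56. The lineage transcription factor genes Sox10 and Olig2 were at -0.09 and -0.42.

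For these families and the oxidative phosphorylation list, a trend of the difference with signal level is argued against as the cause, since medians after that trend was removed were 0.36 for the oxidative phosphorylation list, 0.37 for cytosolic ribosomal, 0.26 for mitochondrial ribosomal and 0.43 for complex I genes. Matching on probe sets per gene, which are few in short genes, did not remove the shift. The 162 genes of these families and that list had a median of 0.30, at percentile 100 among random lists matched on level and on probe sets per gene, whose own median was -0.01. Within the oxidative phosphorylation list, however, members with few probe sets in use were mostly higher (Ndufa1 1.10 with 3, Atp5o 0.64 with 6, but Cox6c -0.09 with 6). Those with more were mostly lower (Ndufv1 -1.06 with 12, Uqcrc1 -0.48 with 20, but Uqcrc2 0.45 with 19). Gene size is thus not excluded as a cause, for that list above all. Transcript length itself and RNA quality were not tested and may differ between the arrays, and a difference between genotypes stays open as a hypothesis. Genes past the rule were more frequent where fewer probe sets are annotated: 2.56% higher and 2.23% lower among 1212 genes with up to 5 probe sets, against 0% and 0.23% among 875 genes with over 40. Both directions were more frequent there, and the median difference was -0.07 with up to 5 probe sets and -0.13 with over 40. These shares thus do not show a shift in 1 direction with gene size.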
